A study of Akkermansia muciniphila with 2 samples.

How the data were processed

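Total RNA of *Akkermansia muciniphila* was isolated with TRIzol and RNeasy columns, depleted of bacterial ribosomal RNA and made into stranded libraries, per the labels' protocols. There was 1 library from the culture with bovine colostrum vesicles (BCEV) and 1 from the culture with phosphate-buffered saline (PBS), as the sample titles state. The values used were the FPKM values deposited by the authors, 1 column per library, with the product name and biotype of each gene. Bowtie, HTSeq and edgeR are named in the submitters' processing notes, without versions or roles. The reference assembly and the settings of these tools are not given in the sources used here. No genome was used here, so genes are given by locus tag, without coordinates, and neighbours are genes with consecutive locus tags. Counting by strand is not stated, so fragments of overlapping or antisense genes may not have been told apart. FPKM divides fragments by gene length and library total. A gene that takes a larger share of 1 library therefore lowers the values of all others, and 2-fold differences were also counted under other scalings.

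The FPKM values moved in steps of whole fragments, which gave the depth. The totals of 10507033 fragments (BCEV) and 9015004 fragments (PBS) were recovered from 231 genes, all of which fitted both totals. The steps fix the totals only up to a common factor, which was set by the assumption that tRNA genes are 70 to 95 nt long. The fragment numbers and counting intervals rest on it. For each of the 2184 genes with a value, the smallest length that gave whole fragments in both libraries was taken, to within 0.6 of a unit of the last decimal printed. Lengths of coding genes were restricted to multiples of 3. Since the smallest fitting length was taken, the fragments given are lower bounds, and counting intervals drawn from them are conservative. The true number is the recovered number or, with few exceptions, a whole multiple of it (99.4% of genes in simulated data). The FPKM ratios do not depend on this step. Recovered fragments summed to 91.6% (BCEV) and 91.4% (PBS) of the totals. A gene of 1 kb with 1 fragment has 0.0952 FPKM in the BCEV library and 0.111 in the PBS library. A count of 0 allows up to 3 fragments, or 0.286 and 0.333 FPKM for such a gene. At 20 FPKM a gene of 1 kb had 210 and 180 fragments.

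Ratios are BCEV to PBS. Log2 ratios were taken on the log2(FPKM + 1) scale, which understates the difference of low genes. Protein-coding genes with a mean of at least 20 FPKM over both libraries were compared, 1865 in all; 273 protein-coding genes below that mean and 63 non-coding genes were left out. With 1 library per group no test was made. Counting intervals are 95% exact (Clopper-Pearson) intervals of the share of a gene's fragments found in the BCEV library, scaled by the library totals. They compare the 2 libraries, not the conditions, and PCR copies are not independent molecules.

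Before the data were examined, 27 gene lists were fixed by patterns in the product names and locus tags, and the lists with at least 5 genes past the filter, 26 in all, were described. The list of non-coding RNA matched only a 5S rRNA-binding protein past the filter (Amuc_1472) and was left out. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn within deciles of mean expression. This describes these libraries and is not a test. Some patterns took in unrelated genes; the lists were kept as fixed, and tightened patterns were tried as an alternative chosen after seeing the data. The rule for named genes, also fixed before, took the 12 largest positive and 12 largest negative log2 ratios and the 5 highest FPKM values of each library. In each list it took the genes at least 2-fold apart, up to 4, or else the 2 with the largest absolute log2 ratio. It also took all of the host-interaction list and of the cluster from Amuc_1098 to Amuc_1102. Any other gene named is said to have been chosen after its values were seen, apart from the higher genes flagged outside the comparison, all of which are named. A pure bacterial culture has no cell types, so the shares of non-coding RNA and of the 10 most abundant genes were given as signs of RNA quality.

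Alternatives were pseudocounts of 0.1 and 10, no filter, a filter at a mean of 100 FPKM, and fold thresholds of 1.5 and 4. Ratios were also centred on their median or rescaled to equal summed FPKM, with and without the 10 most abundant genes, or by TMM factors computed directly on the FPKM (30% trim of ratios, 5% of means, unweighted). Lists were also compared with random lists not matched on expression. Added after seeing the data were the tightened patterns, matching on expression and recovered coding length, and shifts of the ratios along the locus tags.

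The recovery and the statistics were tested on simulated data for the comparison of BCEV with PBS. With 2201 genes drawn from the real means, other library totals and 200 genes given known folds, both totals were recovered exactly. The simulated gene lengths were taken from the recovery itself, with those of some coding genes doubled. Exact totals therefore do not test the common factor, which rests on the assumed length of tRNA genes. Fragments came back exactly for 83.4% of 2182 genes, and exactly or divided by a whole number for 99.4%. Of 50 genes simulated 3 times higher, 100% passed the 2-fold threshold, as did 100% of 50 genes simulated 3 times lower. For 1.5-fold the shares were 0% of 50 higher and 2% of 50 lower genes, and of 1665 genes without a difference 0 passed. Fragments were drawn with counting error only, and ratios were centred before the threshold was applied. These shares therefore leave out the wider spread seen between the real libraries. Counting intervals held the simulated ratio for 95.8% of 1865 genes. They were computed from the simulated fragments and totals themselves, not from the recovered ones. Of 500 lists with no difference, 4.2% lay outside percentiles 2.5 to 97.5. These lists held genes drawn at random with independent values, so the share does not cover neighbouring genes that deviate together. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.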

Results

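*Akkermansia muciniphila* is an anaerobic gut bacterium that lives on the mucus layer and uses mucin as its carbon and nitrogen source. The type strain was cultured with extracellular vesicles from bovine colostrum (BCEV), the first milk after calving, or with phosphate-buffered saline (PBS) as the control. Total RNA was depleted of ribosomal RNA and sequenced, and expression was given as FPKM, the fragments of a gene scaled by its length and by the library total. Each condition had 1 library. As recovered from the values, assuming tRNA genes of 70 to 95 nt, the BCEV library held 10507033 fragments and the PBS library 9015004. With 1 sample per group no difference below has a replicate check, no p-value is given, and each ratio describes these 2 libraries. Intervals are 95% exact (Clopper-Pearson) intervals for the number of fragments. They cover counting error only. They rest on recovered fragments that are lower bounds, so some are too wide, and an interval that takes in 1 may be among these.

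The table held 2201 genes, of which 2138 were protein-coding, 53 were tRNA genes and 9 were rRNA genes. The 6 genes for 16S and 23S rRNA were listed at 0 in both libraries. Non-coding genes took 1.5% of the summed FPKM in the BCEV library and 1.6% in the PBS library. The 10 most abundant genes took 16.4% and 15.5%. In both libraries Amuc_0016, a hypothetical protein, was the most abundant gene, at 47237 FPKM with BCEV and 33687 with PBS, a ratio of 1.40 (95% counting interval 1.39 to 1.41). Next in the BCEV library were 4 more hypothetical proteins, Amuc_0460 at 25667, Amuc_1311 at 21098, Amuc_1021 at 20918 and Amuc_1569 at 17104. In the PBS library Amuc_1311 stood at 25337, Amuc_1021 at 23628, Amuc_0460 at 21152 and Amuc_0998 at 17796.

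The comparison of the BCEV library with the PBS library addressed how the bacterium's transcriptome differs in the presence of the vesicles. The libraries were close. Of 1865 protein-coding genes with a mean of at least 20 FPKM, 1820 (97.6%) differed by less than 1.5-fold. A difference of at least 2-fold on the log2(FPKM + 1) scale was found for 3 genes, 1 higher and 2 lower in the BCEV library. When the ratios were centred on their median, 3 genes were higher and 2 lower. Without the filter on low values, 7 were higher and 18 lower. Across these genes, which are not independent replicates, log2(FPKM + 1) of the libraries correlated with a Pearson r of 0.992 and a Spearman rho of 0.992. The log2 ratio had a median of -0.05 and an SD of 0.23.

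Among the 1865 genes compared, the highest ratio was that of Amuc_1253, glutamate synthase (ferredoxin). It stood at 101 FPKM with BCEV and 46.6 with PBS, 2.17 times higher (95% counting interval 2.06 to 2.30). With a pseudocount of 10 its log2 ratio was 0.98, under the 2-fold threshold. The gene with the preceding locus tag, Amuc_1252, a glutamine synthetase, stood at 163 against 81.9 FPKM, a ratio of 1.99 (interval 1.87 to 2.11) and a log2 ratio of 0.98. Glutamine synthetase and glutamate synthase together form a pathway by which bacteria assimilate ammonium. The second glutamine synthetase gene in the table, Amuc_1258, which was chosen after its values were seen, stood at 182 against 226 FPKM, a ratio of 0.80 (interval 0.77 to 0.84). Glutamate dehydrogenase, Amuc_2051, also chosen after its values were seen, stood at 1288 against 1190 FPKM.

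Among the other genes with the largest positive ratios, most encoded proteins without a known function. Amuc_1979, a hypothetical protein, stood at 39.9 against 19.8 FPKM, on at least 73 and 31 fragments (ratio 2.02, interval 1.31 to 3.18). On the log2(FPKM + 1) scale its ratio was 0.98, under the 2-fold threshold. Amuc_1795 and Amuc_1017 had ratios of 1.68 and 1.63. Amuc_0736, a protein tyrosine phosphatase, stood at 340 against 209 FPKM, 1.62 times higher (interval 1.5 to 1.76). Amuc_0580, an entericidin, a small lipoprotein of the toxin and antidote kind, had a ratio of 1.46. Amuc_0710, a metal ion exporter of the cation diffusion facilitator family, had a ratio of 1.45 (interval 1.38 to 1.54). The ratios of Amuc_0893, Amuc_1629, Amuc_0702 and Amuc_0087 lay between 1.46 and 1.5. The interval of Amuc_0087, from 0.89 to 2.45, took in 1.

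The 2 genes at least 2-fold lower in the BCEV library were Amuc_0399, a hypothetical protein, and Amuc_1922, a putative ferredoxin, an iron-sulfur protein that carries electrons. Amuc_0399 stood at 20.5 FPKM with BCEV and 50.8 with PBS, 2.47 times lower (interval 1.61 to 3.86). With a pseudocount of 10 its log2 ratio was -0.99, under the threshold. Amuc_1922 stood at 75.7 against 172 FPKM, 2.27 times lower (interval 1.76 to 2.95). Both rested on few fragments, at least 33 and 70 for the former and 93 and 181 for the latter. Better counted was Amuc_2170, an abundant hypothetical protein at 2371 against 4436 FPKM, 1.87 times lower (interval 1.79 to 1.95). Amuc_0860, the activating protein of the anaerobic ribonucleotide reductase, which makes deoxyribonucleotides without oxygen, was 1.73 times lower (interval 1.69 to 1.78). Amuc_2028, a MarR family regulator, was 1.74 times lower, and Amuc_1047, the SecE subunit of the preprotein translocase, was 1.73 times lower.

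Further genes at this end were Amuc_0875, a family 16 glycoside hydrolase, at 24.2 against 44.2 FPKM, and Amuc_0095, ribosomal protein L33, at 76.0 against 132 FPKM. Amuc_0103, the ATP-binding part of an ABC transporter, was 1.63 times lower, at 826 against 1347 FPKM. The hypothetical proteins Amuc_1014 and Amuc_1478 were 1.85 and 1.77 times lower. Amuc_0127, a transposase, was 1.71 times lower; fragments of transposase copies can be split between genes, so this value is uncertain.

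**Figure D1:**
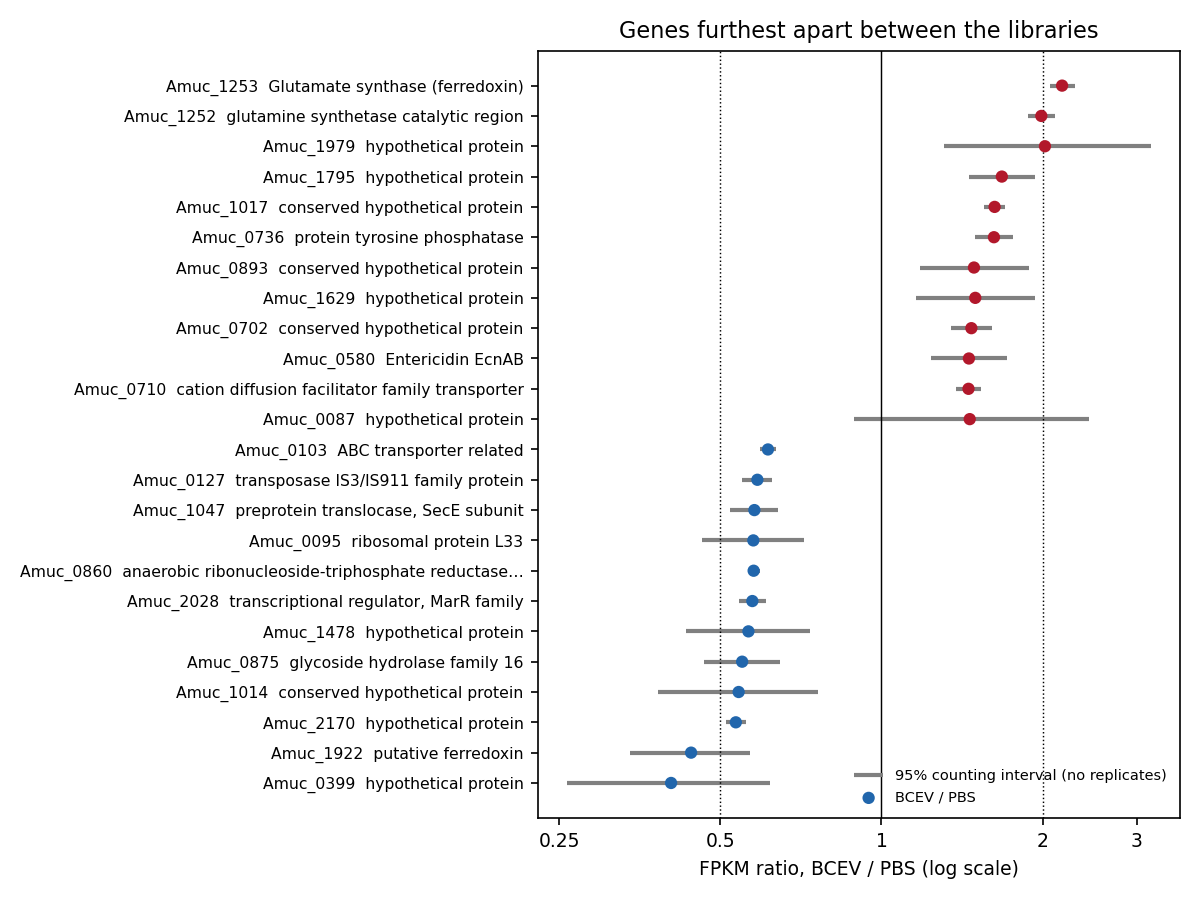
FPKM ratio of the BCEV to the PBS library (log scale) for the 12 genes with the largest positive and the 12 with the largest negative log2 ratio among 1865 genes. Points are ratios, bars are 95% counting intervals without replicate error, and dotted lines mark 2-fold. Amuc_1253 lies at 2.17 and Amuc_0399 at 0.40.

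The ribosomal protein genes were lower as a group in the BCEV library. Of 53 members of the list, 44 were lower and 9 higher, and 41 lay below the median of all genes. None was 2-fold apart. Their median log2 ratio was -0.25, below each of 10000 random lists of the same size matched on mean expression, whose central 95% ran from -0.09 to 0.03. Ribosomal protein L33 (Amuc_0095), with a log2 ratio of -0.79, and ribosomal protein S8 (Amuc_0927), with -0.67, had the largest differences. The genes for ribosomal proteins L20, L35 and L28 went the other way. They were chosen after their values were seen, and the highest, L20 (Amuc_1557), stood at 1816 against 1391 FPKM. The other lists of gene expression lay within the range of random lists. Translation factors and tRNA ligases had a median of -0.09 in 35 genes (percentile 6.84), with arginyl-tRNA synthetase (Amuc_2169) at -0.35 and aspartyl-tRNA synthetase (Amuc_1396) at -0.32. RNA polymerase and sigma factors had a median of -0.10 in 11 genes (percentile 12.2), with the beta' subunit (Amuc_1040) at -0.36 and the beta subunit (Amuc_1041) at -0.35.

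Amino acid biosynthesis genes lay above the other genes. Of 59 members, 36 were higher and 23 lower in the BCEV library, 44 lay above the median of all genes, and 1, the glutamate synthase gene, was at least 2-fold higher. The median log2 ratio of 0.04 was at percentile 99.6 of matched random lists, whose central 95% ran from -0.09 to 0.02. The 6 genes with consecutive locus tags for tryptophan synthesis, Amuc_1531 to Amuc_1536, described after their values were seen, were all higher, with log2 ratios from 0.25 to 0.46. The last, tryptophan synthase alpha subunit (Amuc_1536), stood at 695 against 506 FPKM.

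Genes for defence against oxygen and oxidants had a median log2 ratio of 0.13 in 13 members, at percentile 99.2 of matched random lists but at percentile 95.5, inside the central 95%, when the ratios were shifted along the locus tags, which keeps neighbouring genes together. Of these 8 were higher and 5 lower. A thioredoxin (Amuc_0691) had the largest difference of the list, at 2126 against 2844 FPKM, a log2 ratio of -0.42. A protein with a thioredoxin domain (Amuc_0147) stood at 5625 against 4555 FPKM, a log2 ratio of 0.30. Members chosen after their values were seen were catalase (Amuc_2070), which breaks down hydrogen peroxide, at 1622 against 1377 FPKM, superoxide dismutase (Amuc_1592), at 4526 against 4127, and a rubrerythrin (Amuc_2072), at 815 against 672. Chaperones and ATP-dependent proteases had a median of 0.06 in 13 genes (percentile 89.0). ClpB (Amuc_0836), a disaggregase of heat-damaged proteins, stood at 4916 against 3651 FPKM, 1.35 times higher. The outer membrane chaperone Skp (Amuc_0405) had a log2 ratio of -0.27.

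**Figure D2:**
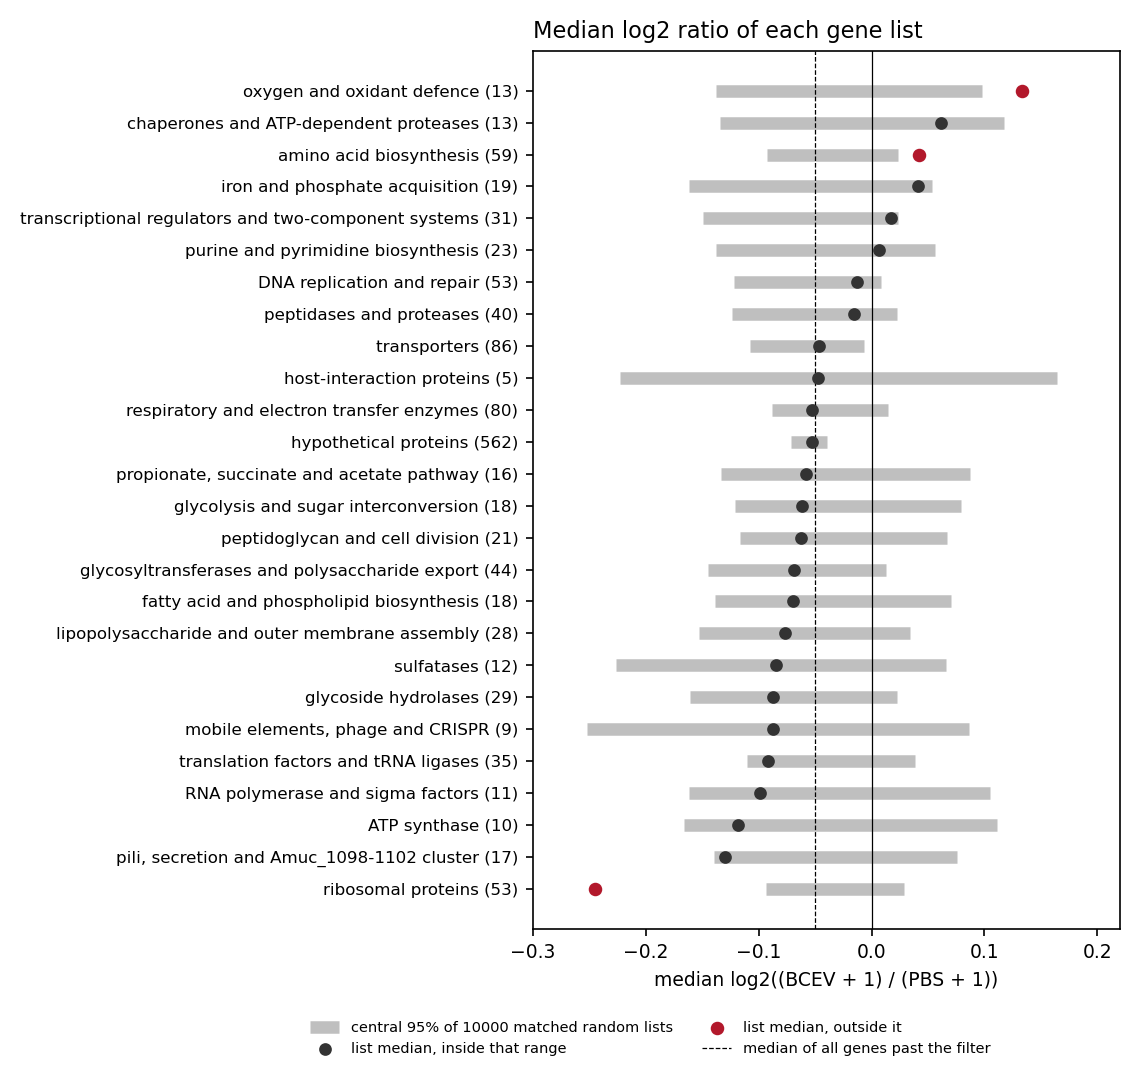
Median log2 ratio of the BCEV to the PBS library for 26 gene lists, with the number of genes past the filter in brackets. Points are list medians, grey bars the central 95% of 10000 random lists matched on mean expression, and the dashed line the median of all genes. Ribosomal proteins at -0.25 lie below their bar; oxygen and oxidant defence at 0.13 and amino acid biosynthesis at 0.04 lie above theirs. The former lies inside the central 95% (percentile 95.5) when neighbouring genes are kept together.

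Genes for mucus use and contact with the host did not stand apart. Glycoside hydrolases, which cleave mucin glycans, had a median log2 ratio of -0.09 in 29 genes (percentile 32.8); the family 16 enzyme Amuc_0875 was at -0.84 and the family 95 enzyme Amuc_0186 at -0.42. Sulfatases, which remove sulfate from mucin, had a median of -0.08 in 12 genes (percentile 41.4), with Amuc_1655 at -0.53 and Amuc_0953 at -0.37. The interval of the ratio of Amuc_1655 took in 1, but its 45 and 56 fragments are lower bounds, so the interval may be too wide. Peptidases and proteases had a median of -0.02 in 40 genes (percentile 82.7), with the M28 peptidase Amuc_0187 at -0.64 and the M50 peptidase Amuc_0033 at -0.45.

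The 5 proteins named in work on effects of the bacterium on its host had a median of -0.05 (percentile 41.4). Amuc_1100, an outer membrane protein known for its action on the host receptor TLR2, stood at 661 FPKM with BCEV and 772 with PBS, 1.17 times lower (interval 1.11 to 1.23). Amuc_1409 was 1.17 times higher (interval 1.14 to 1.20) and Amuc_2172, an acetyltransferase, 1.13 times higher (interval 1.06 to 1.21). The ratio of Amuc_1434 was 0.94 (interval 0.91 to 0.97). That of Amuc_1831 was 0.97, its interval from 0.91 to 1.02 took in 1, and its log2 ratio of -0.05 turned positive when the ratios were centred on their median or scaled by TMM factors. Around Amuc_1100, in what is thought to be a pilus assembly cluster, Amuc_1098 was 1.18 times lower (interval 1.17 to 1.19). The ratios of Amuc_1099, Amuc_1101 and Amuc_1102 were 1.03, 1.04 and 1.02. The list of pili and secretion genes, which holds this cluster, had a median of -0.13 in 17 genes (percentile 3.54). Besides SecE, at -0.79, the twitching motility protein Amuc_0166 had the largest difference of that list, at -0.42. Against lists matched also on recovered coding length the percentile was 1.39, against unmatched lists 10.3, and under shifts of the ratios along the locus tags 13.6.

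The lists of energy metabolism lay inside the range of random lists. The ATP synthase list had a median of -0.12 in 10 genes (percentile 9.65). Its fixed pattern also took in ATPase subunits of ABC transporters, among them the 2 members with the largest differences, Amuc_0320 at -0.19 and Amuc_1852 at -0.14. All 10 had negative log2 ratios as deposited, and 2 lay above the median of all genes. Respiratory and electron transfer enzymes had a median of -0.05 in 80 genes (percentile 30.4), 1 of them at least 2-fold higher and 1 lower. These were the glutamate synthase gene, named for its ferredoxin, and the ferredoxin Amuc_1922; the pattern also matched dehydrogenases outside respiration. With a tightened pattern, chosen after seeing the data, 41 genes had a median of -0.09 (percentile 4.15). The pathway to propionate, succinate and acetate, the fermentation products of the bacterium, had a median of -0.06 in 16 genes (percentile 26.9). The flavoprotein (Amuc_0985) and cytochrome b (Amuc_0986) subunits of succinate dehydrogenase or fumarate reductase were at -0.39 and -0.38. Glycolysis and sugar interconversion had a median of -0.06 in 18 genes (percentile 21.8), with glucose-6-phosphate isomerase (Amuc_1975) at -0.36 and a phosphoglycerate mutase (Amuc_0772) at 0.34.

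Biosynthesis of nucleotides and lipids gave similar values. Purine and pyrimidine biosynthesis had a median of 0.01 in 23 genes (percentile 82.7); the reductase-activating protein Amuc_0860 was at -0.79 and a phosphoribosylformylglycinamidine synthase (Amuc_0534) at -0.33. Fatty acid and phospholipid biosynthesis had a median of -0.07 in 18 genes (percentile 23.1), with acyl carrier protein (Amuc_0975) at -0.44 and malonyl-CoA transacylase (Amuc_1507) at -0.39.

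In the envelope lists, lipopolysaccharide and outer membrane assembly had a median of -0.08 in 28 genes (percentile 32.9). The outer membrane lipoprotein of an efflux system, Amuc_0105, was 1.60 times lower, and an autotransporter, Amuc_1722, was at -0.49. Peptidoglycan and cell division had a median of -0.06 in 21 genes (percentile 20.4), with a D-alanine ligase (Amuc_0661) at -0.34 and an amidase (Amuc_1211) at -0.27. Glycosyltransferases and polysaccharide export had a median of -0.07 in 44 genes (percentile 46.0). The members with the largest differences were the group 1 glycosyltransferases Amuc_2088 at -0.57 and Amuc_2089 at -0.50. Transporters had a median of -0.05 in 86 genes (percentile 66.2), led by Amuc_0103 at -0.70 and Amuc_0105 at -0.68.

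Iron and phosphate acquisition had a median of 0.04 in 19 genes (percentile 95.7), with a zinc/iron permease (Amuc_1483) at -0.29. The pattern matched other iron-sulfur proteins and phosphohydrolases, among them an oxidoreductase subunit (Amuc_1214) at -0.27, and only 4 of the 19 genes remained when it was tightened. Transcriptional regulators and 2-component systems had a median of 0.02 in 31 genes (percentile 96.5). The percentile was 97.9 at a mean of at least 100 FPKM and 98.8 under shifts along the locus tags, both outside the central 95%. The largest differences were those of the MarR regulator Amuc_2028, at -0.80, and a MerR regulator (Amuc_1810), at 0.37. DNA replication and repair had a median of -0.01 in 53 genes (percentile 91.3), with a DEAD/DEAH box helicase (Amuc_1212) at -0.42 and the recombinase XerC (Amuc_0273) at -0.40. Mobile elements, phage and CRISPR genes had a median of -0.09 in 9 genes (percentile 39.6). Besides the transposase Amuc_0127, Amuc_0551, labelled a phage SPO1 DNA polymerase-related protein, was at -0.35. The 562 hypothetical proteins had a median of -0.05 (percentile 48.3) and held 1 gene at least 2-fold apart on the log2(FPKM + 1) scale, Amuc_0399.

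**Figure D3:**
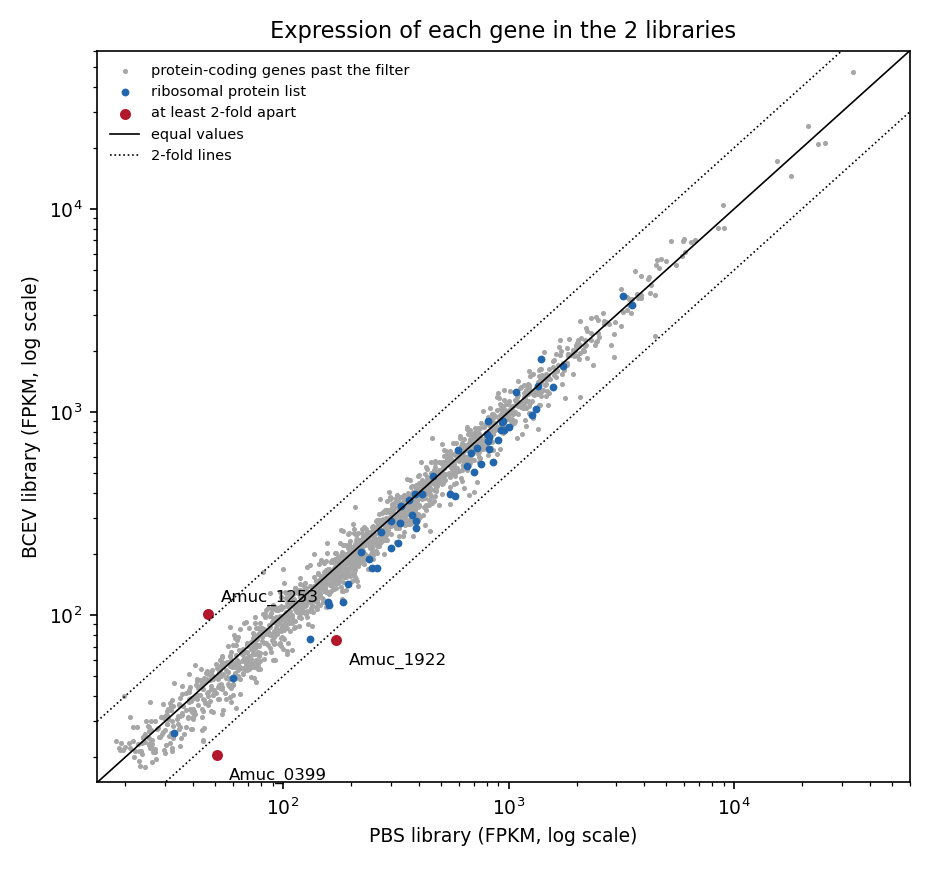
FPKM of each of 1865 protein-coding genes in the PBS library (horizontal) and the BCEV library (vertical), both on log scales. The solid line marks equal values and the dotted lines 2-fold; red points are the 3 genes at least 2-fold apart on the log2(FPKM + 1) scale and blue points the 53 ribosomal protein genes, of which 44 were lower in the BCEV library.

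The spread between the libraries was wider than counting error. In the lowest decile of mean expression the SD of the log2 ratio was 0.29 and the median counting error 0.12. In the highest decile these values were 0.22 and 0.02. The median log2 ratio also differed by expression, from -0.13 in the lowest decile to 0.02 in the highest, though it did not rise at each step. Weakly expressed genes were thus lower in the BCEV library as a class. The scalings tried shift all ratios nearly alike and do not remove this. By counting alone 414 genes had an interval above 1, 769 an interval below 1, and 682 an interval that took in 1. The split of all genes was 744 higher and 1121 lower. It was the same at equal summed FPKM, which is no check, since the deposited sums were already 1.09896e+06 (BCEV) and 1.09895e+06 (PBS). The split was 800 and 1065 with the 10 most abundant genes left out of the sum. With TMM factors, which set the trimmed mean of the ratios to 0, it was 952 and 913. A counting interval compares 2 libraries, and without a further culture per condition the spread between cultures is unknown.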

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

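Outside the comparison lay 336 genes, 63 non-coding and 273 protein-coding with a low mean. In 4 of them the BCEV library was at least 2-fold higher on the log2(FPKM + 1) scale and the counting interval of the ratio lay above 1. With 336 genes looked at, intervals uncorrected for their number and no replicate, chance is not excluded. Amuc_0734, a hypothetical protein, stood at 14.4 FPKM with BCEV and 4.51 with PBS, 3.19 times higher (95% counting interval 1.95 to 5.43). The gene 2 locus tags on, Amuc_0736, is among the largest positive ratios of the comparison. Amuc_1300, adenylylsulfate reductase, an enzyme of sulfate assimilation, rested on at least 19 and 3 fragments, a ratio of 5.43 (interval 1.60 to 28.7). The tRNA gene Amuc_R0045 (tRNA-Phe) had a ratio of 2.83 (interval 1.36 to 6.44) and Amuc_R0060 (tRNA-Asp) a ratio of 2.30 (interval 1.55 to 3.50). Another tRNA-Asp gene, Amuc_R0022, chosen after its values were seen, went the other way and was 2.16 times lower (interval 1.09 to 4.48). In all, 4 tRNA genes were at least 2-fold lower with an interval below 1. Short RNAs are lost unevenly in RNA isolation and library preparation, and copies of a tRNA gene share fragments, so the tRNA values are uncertain.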

How the results depend on the processing

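The counts of genes at least 2-fold apart, 1 higher and 2 lower, are small, so that single genes decide them. With a pseudocount of 0.1, 2 genes were higher; with a pseudocount of 10, 0 were higher and 1 lower; with a filter at a mean of 100 FPKM, 0 and 1. Centring on the median and TMM factors each gave 3 higher genes. Without a filter 7 were higher and 18 lower. At 1.5-fold 6 were higher and 39 lower, and at 4-fold 0 and 0. Amuc_1922 passed under every pseudocount, filter and scaling tried.

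Centring shifts all ratios alike and so could not move a list percentile. Equal summed FPKM could hardly do so, since the deposited sums were already 1.09896e+06 (BCEV) and 1.09895e+06 (PBS). The other scalings also shifted the ratios nearly alike. Of 292 list percentiles recomputed, with these settings counted, 288 stayed on the same side of the central 95% of lists. That share therefore overstates how far the lists were tested. The exceptions were pili and secretion genes matched on coding length (percentile 1.39), transcriptional regulators at a mean of 100 FPKM (97.9) and under shifts along the locus tags (98.8), and oxygen and oxidant defence under those shifts (95.5). The length matching and the shifts were added after seeing the data. The cause was not tested. With tightened patterns iron and phosphate acquisition kept 4 genes, too few to describe.

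Without a filter Pearson r was 0.993, Spearman rho 0.995 and the SD of the log2 ratio 0.29; at a mean of 100 FPKM these were 0.988, 0.986 and 0.21, and with a pseudocount of 10 the SD was 0.21. Of 590 values of the 76 named genes, 58 left their counting interval and 0 of the 3 genes at least 2-fold apart changed sign. The 590 include values under other filters, which cannot change a gene's ratio. They also include values at equal summed FPKM, which hardly could, as the sums were already almost equal. The share that stayed therefore overstates how far the ratios were tested. Of all 76, 1 gene changed sign, Amuc_1831. Centring shifted all ratios by 0.05 and TMM factors by 0.06. No paired analysis was possible because each group had 1 sample.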

Other observations

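Several runs of genes with consecutive locus tags differed in 1 direction. They were chosen after their values were seen, and their intervals cover counting error only. For scale, of all 1865 genes compared 744 were higher and 1121 lower in the BCEV library, and 769 had an interval below 1. The genes Amuc_0102 to Amuc_0105, which encode the parts of an efflux transporter, were all lower in the BCEV library, with log2 ratios from -0.70 to -0.47. In the region from Amuc_2081 to Amuc_2096, which holds glycosyltransferases and a polysaccharide biosynthesis protein, 15 of 16 genes were lower, with a median log2 ratio of -0.40, and all 15 had an interval below 1. The 11 genes from Amuc_1604 to Amuc_1614, which encode NADH dehydrogenase, the proton-pumping entry of the respiratory chain, were all lower, with log2 ratios from -0.43 to -0.09 and a median of -0.18. Glutaminase (Amuc_0038), which releases ammonia from glutamine, and the amino acid permease beside it (Amuc_0037) had log2 ratios of 0.41 and 0.42, on the same side as glutamate synthase (Amuc_1253) and the glutamine synthetase gene Amuc_1252 but not the glutamine synthetase gene Amuc_1258.

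Among the 336 genes outside the comparison, 11 were at least 2-fold lower in the BCEV library with a counting interval below 1, 7 of them protein-coding genes with a low mean. The best counted of these, chosen after its values were seen, was Amuc_0627, a conserved hypothetical protein. It stood at 8.76 against 21.4 FPKM, 2.44 times lower (interval 1.99 to 3.01). The tRNA gene Amuc_R0033 (tRNA-Trp), also chosen after its values were seen, stood at 38.8 against 121 FPKM, 3.12 times lower (interval 2.04 to 4.88).

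In the 3 patterns weighed next, the tests of counting error and of shared fragments for the glutamine synthetase pair were chosen after the result was seen, as was the number of cultures per group. The length matching and the shifts along the locus tags were added after seeing the data. The first pattern is the lower ribosomal protein genes. The list's median lay at percentile 0 of 10000 lists matched on expression and recovered coding length. The recovered length can be a fraction of the true length, so the matched lists can hold longer genes. Short genes as the cause are therefore not excluded. Neighbouring genes deviating together were argued against, since the list's median deviation stood at percentile 0 of the 1864 shifts of the values along the locus tags. Culture-to-culture variation stays open too. With 1 culture and 1 library per group, differences between cultures or libraries cannot be told apart from an effect of the vesicles. Other causes were not tested.

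The second pattern is the pair Amuc_1252 and Amuc_1253. Counting error was argued against: with intervals widened for the number of genes compared, the lower bounds were 1.75 and 1.94. Fragments shared with the other glutamine synthetase gene would draw the ratios of both genes together, but the interval of Amuc_1258 ended at 0.84. Culture-to-culture variation stays open, with 1 culture per group. Differences between the library preparations stay open as well, and an effect of the vesicles was not tested apart from either.

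The third pattern is that genes with consecutive locus tags deviated together. Over 1701 neighbouring pairs the deviations from the median of the expression decile correlated with a Pearson r of 0.22 across genes, which are not independent replicates, against at most 0.09 in 10000 shuffled orders. Fragments spanning the border of 2 genes were argued against, since r was 0.34 over 285 pairs of long genes (at most 0.24 in shuffled orders). Low expression was argued against by an r of 0.21 at a mean of at least 100 FPKM. Variation between cultures or between library preparations stays open, with 1 culture and 1 library per group. Other causes of neighbours deviating together were not tested.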
